A study of Homo sapiens with 8 samples.

How the data were processed

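Expression was measured on 8 Affymetrix U133 Plus 2 arrays hybridized with biotin-labelled RNA of the human embryonic stem cell line Sheff 4. The labels give 3 untreated arrays and 3 arrays treated with 20 µM S1P, both on MEFs. A further 2 untreated arrays, labelled replicates 2 and 3, have titles and descriptions that name Matrigel. The treatment text is the same for all arrays and names MEFs, so the surface of these 2 arrays rests on their titles and descriptions. The deposited values are intensity values, 1 MAS5 signal per probe set on a linear scale. MAS5 is named per the submitters' processing notes, and its version and scaling target are not given in the sources used here. The 2% trimmed mean was 100 on every array, so the table was taken as already scaled per array and used as deposited. The lowest signal was 0 and the highest 7890. Scaling of this kind makes all values relative to the other probe sets of an array. For arrays, precision is limited by their number.

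Probe sets were named through the platform annotation supplied with the data. Of 54675 probe sets, 62 were controls, 41091 had 1 gene symbol, 1801 had several and 11721 had none. Only those with 1 symbol were used. Of 19777 Entrez identifiers, 19735 matched the reference gene table (GRCh38.p14), which was used only for names, neighbouring genes and gene lengths, and 0 symbols changed. POU5F1 and SPHK2 had no probe set with a single symbol. For each of 19775 genes the probe set with the highest mean was kept. Statements on a gene's other probe sets cover those above the filter, while the mean of all probe sets also takes the dimmer ones. Probe sets of a gene could disagree: of 1016 genes called between S1P and untreated cells that had further probe sets above the filter, 643 had all of them in the same direction, and for Matrigel 912 of 1358.

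Values were transformed as log2(signal + 4), where 4 is the 20th percentile of all signals, so fold changes are on that scale and understate the change of dim genes. Genes below the 40th percentile of mean log2 were left out, which left 11865. A limma fit (limma 3.58.1 in R 4.3.3; lmFit and eBayes with an intensity trend) over all 8 arrays had 3 groups and no block. Two-sided p-values were adjusted by Benjamini-Hochberg over the genes of each of 3 comparisons, with 0.05 as the threshold. Means and SDs are of the linear signal, and SEs are of the fitted log2 difference.

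A total of 30 gene lists, fixed before the data were examined, were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists. They cover pluripotency, Nodal, Activin and TGF-beta, BMP, Wnt, FGF and ERK, immediate early, YAP and SRF, S1P receptors and metabolism, anti-apoptotic, pro-apoptotic, p53, G1 and S phase, G2 and M phase, cell cycle inhibitors, junctions, integrins, fibroblast and feeder, neuroectoderm, mesoderm, endoderm, trophoblast, matrix enzymes, glycolysis and hypoxia, cholesterol, unfolded protein, heat shock, metallothionein, ribosomal, respiratory chain and interferon genes. Camera was also run with an estimated correlation. That version also rests on the few residual degrees of freedom of the arrays, so a call lost under it need not be lost through correlation. The fry test asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes.

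Genes were named by a rule also fixed then. It takes the 8 largest rises and 8 largest falls that passed with arrays of both groups not overlapping, up to 3 members per list with the smallest p that passed over all genes or over the list alone, and POU5F1, NANOG, SOX2, S1PR1 to S1PR5, SPHK1 and SPHK2. For Matrigel against S1P it takes the 4 largest rises and 4 largest falls, filled by the smallest p where fewer passed. The text below gives only part of the genes that the rule takes. Near-identical or closely similar genes, EIF3C and MT1M among them, and overlapping genes are given as uncertain. SPRY4-IT1, MIR181A2HG, LOC114224, TUBA4B, POU5F1P3, POU5F1P4, GADD45GIP1 and CCDC152 overlap another gene, and their probe sets were not checked against it.

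The test was run on simulated data in which 100 genes changed by a log2 of 1 and 100 by 2. For S1P against untreated cells 58% and 98% were recovered, with 18 false among 174 calls. For Matrigel against MEFs it was 54% and 91% (15 of 160), and for Matrigel against S1P 50% and 88% (8 of 146). Of 29 unchanged lists 0 were called. The simulated genes varied independently, whereas the estimated correlation within a list reached 0.62 in the data. The simulation therefore cannot test calls made at the preset correlation. The correlation of the S1P and Matrigel differences was compared with 100 simulations of unchanged groups sharing the same untreated arrays.

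Alternatives fixed beforehand changed the offset, the filter, the normalization, the arrays in the fit, the intensity trend, array weights, the choice of probe sets, the replicate number as a block, the threshold and each array in turn. Scaling to the bacterial hybridization controls, and quantile normalization with an estimated correlation for 3 lists, were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.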

Results

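Gene expression was measured in Sheff 4, an established line of human embryonic stem cells, on 8 Affymetrix U133 Plus 2 arrays, which carry 54675 probe sets for human transcripts. Cells grown on mouse embryonic fibroblast (MEF) feeder layers were either left untreated (3 arrays) or given 20 µM sphingosine-1-phosphate (S1P), a signalling lipid that acts through G-protein-coupled receptors (3 arrays). A further 2 arrays came from untreated cells that the titles and descriptions place on Matrigel, a basement membrane extract, in place of feeder cells. All 8 arrays had a trimmed mean signal of 100, and median signals lay between 17.1 and 27.3. Nothing in the labels says whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

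The groups also differed in transcripts that no human cell makes. Probe sets for the 4 Bacillus poly-A controls (dap, lys, phe and thr), which are added to RNA before labelling, averaged 3.63 ± 0.24 on the log2 scale (SD, n = 3) on the untreated MEF arrays. They averaged 7.18 ± 0.43 (n = 3) on the S1P arrays and 7.65 ± 0.07 (n = 2) on the Matrigel arrays. The S1P and untreated MEF arrays thus differed by 3.55 (SE 0.29) and the Matrigel and untreated MEF arrays by 4.02 (SE 0.15). The Matrigel and S1P arrays differed by 0.47 (SE 0.26). The ratio of 3' to 5' actin signal, a measure of RNA integrity and labelling, was 17.0 ± 1.6, 6.77 ± 0.48 and 9.69 ± 0.30 on the untreated MEF, S1P and Matrigel arrays. The same ratio for GAPDH was 1.64 ± 0.13, 1.54 ± 0.041 and 1.68 ± 0.064, and in it the untreated MEF arrays overlapped with both other groups. They lay apart from all other arrays in the poly-A controls and the actin ratio, so for both comparisons with them the processing of the RNA and the group cannot be told apart. The Matrigel and S1P arrays overlapped in the mean of the poly-A controls but not in dap, the brightest of them, or in either ratio.

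**Figure D1:**
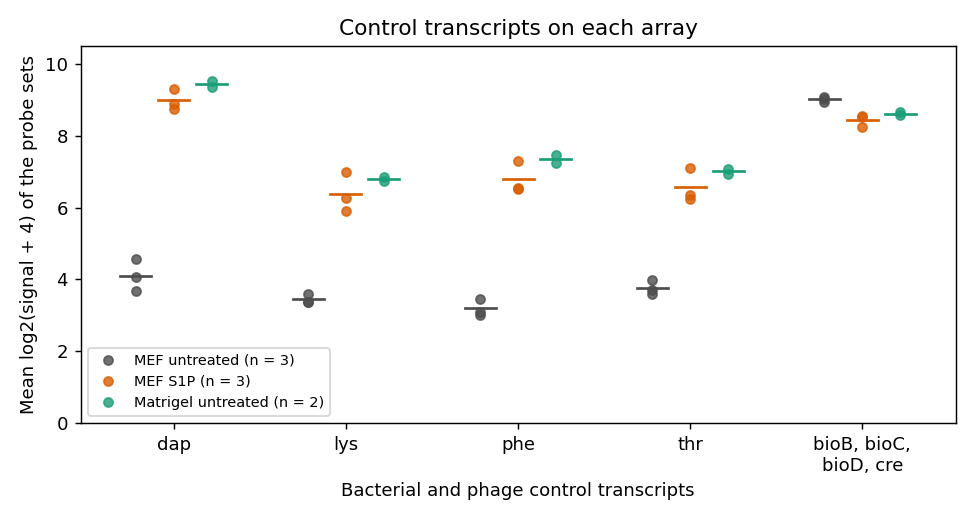
Mean log2(signal + 4) of the probe sets for 4 poly-A controls and for the hybridization controls (bioB, bioC, bioD and cre), with 1 point per array and a line at each group's mean. The poly-A controls averaged 3.63 on the untreated MEF arrays against 7.18 and 7.65 on the S1P and Matrigel arrays, and the hybridization controls averaged 9.01, 8.44 and 8.61.

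The first comparison asked which genes differed between S1P-treated and untreated cells on MEFs, with attention to survival, proliferation and the undifferentiated state. As lists, targets of YAP and SRF and markers of fibroblasts were shifted up on the S1P arrays with a preset correlation (adjusted p = 0.098 and adjusted p = 0.11 with an estimated correlation). NANOG and the Nodal antagonist LEFTY1 were lower. THBS1, which encodes the matrix protein thrombospondin 1, had a signal of 1580 ± 229 on the S1P arrays and 129 ± 79.6 on the untreated arrays (SD, n = 3 each), a log2 difference of 3.72 (SE 0.38, adjusted p = 0.00012). INHBA, which encodes the activin A subunit, rose from 18.8 ± 2.10 to 208 ± 22.8 (log2 3.21, SE 0.23, adjusted p = 3.1e-05). LEFTY1 fell from 793 ± 380 to 114 ± 36.3 (log2 -2.66, SE 0.35, adjusted p = 0.00046). NANOG, a core transcription factor of embryonic stem cells, fell from 3080 ± 192 to 1620 ± 76.1 (log2 -0.92, SE 0.10, adjusted p = 0.00015).

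Of 11865 genes tested, 1921 passed an adjusted p of 0.05, with 749 higher and 1172 lower on the S1P arrays. A log2 difference above 1 in size was seen for 385 of the higher and 162 of the lower genes. The signals are scaled to a common trimmed mean, so directions are relative to the other genes on the array, and the median of all genes was -0.06. When the hybridization controls were made equal instead, the median of all genes became 0.51 and 4141 genes passed, 4090 of them higher. The count was 882 with array medians set equal (median of all genes -0.18), 1178 without untreated MEF replicate 2 and 1237 without S1P replicate 3.

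Among the largest rises were SPRY4-IT1, a noncoding RNA from an intron of SPRY4 (125 ± 31.9 against 4.33 ± 1.76, log2 3.94, SE 0.32), and BHLHE40, a transcriptional repressor (3.31, SE 0.25). EDN1, which encodes endothelin 1, rose by 3.18 (SE 0.30), although 1 of its other 2 probe sets moved the opposite way. EGR3, an immediate early transcription factor, rose by 3.50 (SE 0.70), the metallothionein MT1M by 3.32 (SE 0.69) and the membrane protein gene EMP1 by 3.16 (SE 0.36). The untreated signals of SPRY4-IT1, MT1M (9.23 ± 12.4) and EMP1 (11.5 ± 8.23) were low, so the size of their differences depends on the offset of 4. MT1M belongs to a family of closely similar genes, so which member was measured is uncertain. The largest falls included NPM3, a nucleoplasmin family member (log2 -2.76, SE 0.27), the arginine methyltransferase PRMT1 (-2.43, SE 0.21) and the pro-apoptotic BAX (-2.32, SE 0.44). GADD45GIP1 fell by 2 on the log2 scale (SE 0.31). COPE, a coat protein of transport vesicles, had a difference of -2.43 (SE 0.56, adjusted p = 0.011) that did not pass without the intensity trend in the variance and was -1.57 without S1P replicate 2. With averaged probe sets the differences of BHLHE40, SPRY4-IT1, PRMT1, GADD45GIP1 and COPE were over 1.5 times smaller but passed, as were those of THBS1, INHBA, COL1A1, KLF6, LEF1 and SLC30A1. The pseudogenes POU5F1P3 (-2, SE 0.26) and POU5F1P4 (-2.02, SE 0.33) also fell. They are near-identical to POU5F1, which encodes OCT4, and their probe sets can cross-hybridize, so which copy was measured is uncertain. POU5F1 and the kinase gene SPHK2 had no probe set of their own and were not analysed here.

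**Figure D2:**
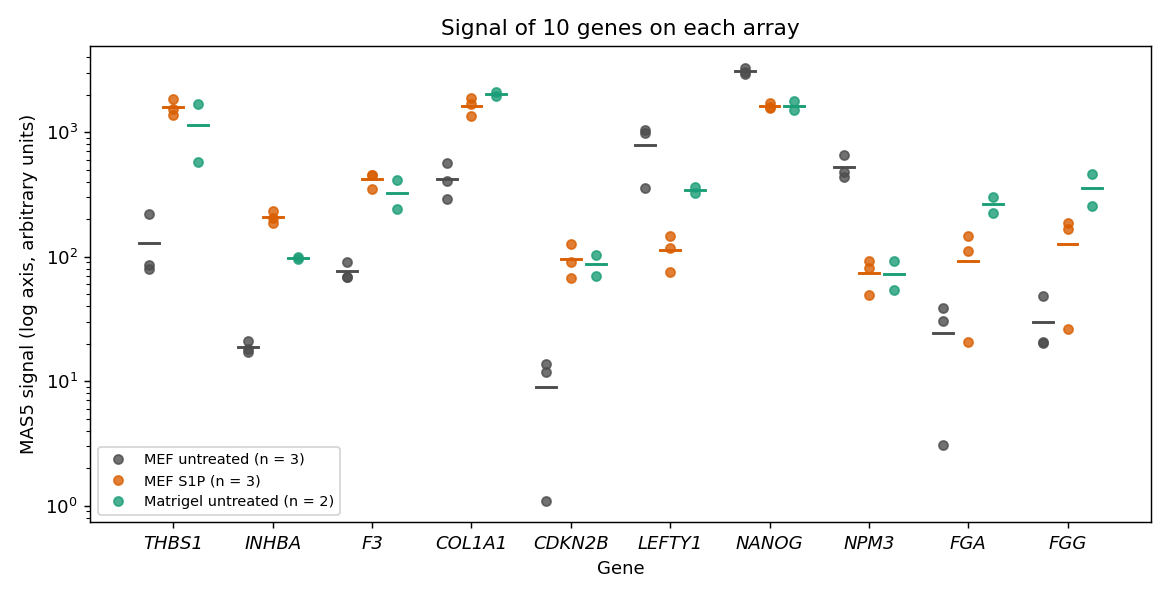
MAS5 signal of 10 genes on a log axis, with 1 point per array and a line at each group's mean. THBS1, INHBA and F3 were higher on the S1P and Matrigel arrays than on the untreated MEF arrays, and NANOG and NPM3 were lower. The fibrinogen genes FGA and FGG were highest on average on the Matrigel arrays.

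Of 30 gene lists, camera with a preset correlation called 18 shifted, 14 up and 4 down, and fry called 13. With an estimated correlation 0 of these calls held, here and in the comparisons that follow. Targets of YAP and SRF had the smallest p. Of 25 tested targets of YAP and SRF, which respond to cell tension and the actin cytoskeleton, 18 rose, 0 fell and 7 did not pass, and 20 rose when p was adjusted over the list alone. Their median log2 difference was 0.96 (camera adjusted p = 6.42e-15, and adjusted p = 0.098 with an estimated correlation). THBS1, F3 (tissue factor, log2 2.40, SE 0.23) and CRIM1 (1.69, SE 0.18) led this list. Of 17 immediate early genes, 11 rose and 0 fell, with the same counts adjusted over the list alone (median 0.91, adjusted p = 5.3e-06, but adjusted p = 0.31 with an estimated correlation). ATF3 rose by 1.55 (SE 0.22), KLF6 by 1.66 (SE 0.25), and DUSP1, a MAP kinase phosphatase, by 1.42 (SE 0.25). ATF3 and DUSP1 did not pass when the probe sets of a gene were averaged. Of 19 FGF and ERK response genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.16 (adjusted p = 0.0241, and 0.31 as the adjusted p with an estimated correlation). PHLDA1 (2.17, SE 0.26) and EPHA2 (1.58, SE 0.21) rose, and the list was not shifted without untreated MEF replicate 1 (adjusted p = 0.15) or S1P replicate 1 (adjusted p = 0.12).

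Markers of fibroblasts and feeder cells rose as a list, on the arrays that also had 3.55 more poly-A control signal on the log2 scale. Of 28 tested, 15 rose and 0 fell, the same as adjusted over the list alone, with a median of 1.09 (adjusted p = 1.55e-12, and adjusted p = 0.11 with an estimated correlation). COL1A1, a fibrillar collagen gene, rose from 420 ± 137 to 1630 ± 272 (log2 1.98, SE 0.20), with 2 of its other 4 probe sets moving the same way. TIMP3, a metalloproteinase inhibitor, rose by 2.80 (SE 0.30) with all 3 of its other probe sets. PDGFRA, a growth factor receptor, had a difference of 2.24 (SE 0.21), but its 1 other probe set above the filter moved the opposite way, and the mean of all its probe sets did not pass. Of 19 matrix enzymes and plasminogen genes, 8 rose and 0 fell (9 and 1 adjusted over the list alone; median 0.62, adjusted p = 1.44e-05, and 0.11 as the adjusted p with an estimated correlation). LOX (2.24, SE 0.28) and the urokinase gene PLAU (2.75, SE 0.36) were among them. Of 22 integrin and basement membrane genes, 12 rose and 1 fell, as they did adjusted over the list alone (median 0.58, adjusted p = 1.74e-06, and 0.11 as the adjusted p with an estimated correlation). They included the integrin subunits ITGA2 (1.5, SE 0.26) and ITGAV (0.83, SE 0.11), of which ITGAV did not pass with array medians set equal.

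Lists of signalling targets and lineage markers followed. Of 16 BMP signalling targets, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.65 (adjusted p = 6.93e-05, and adjusted p = 0.26 with an estimated correlation). GREM1, a BMP antagonist, rose by 2.55 (SE 0.21), BMP2 by 1.25 (SE 0.15) and the BMP pseudoreceptor BAMBI by 1.06 (SE 0.16). Of 15 Wnt targets and antagonists, 6 rose and 1 fell, also adjusted over the list alone (median 0.51, adjusted p = 0.00107, and adjusted p = 0.22 with an estimated correlation), led by LEF1 (2.21, SE 0.28) and LGR5 (1.30, SE 0.23). Of 12 mesoderm markers, 2 rose (6 rose and 1 fell adjusted over the list alone; median 0.68, adjusted p = 0.00109, and adjusted p = 0.26 with an estimated correlation), among them SNAI2 (1.90, SE 0.34). Of 12 trophoblast markers, 5 rose (6 adjusted over the list alone; median 0.68, adjusted p = 0.000166, and adjusted p = 0.23 with an estimated correlation), with IGFBP3, which binds insulin-like growth factors, at 1.87 (SE 0.26). Of 18 neuroectoderm markers, 3 rose and 1 fell, as they did adjusted over the list alone (median 0.63, adjusted p = 0.00217, and adjusted p = 0.34 with an estimated correlation). The member that fell was OTX2 (-0.61, SE 0.14), whose call was lost in 4 of 21 alternatives, quantile normalization among them. Of 17 endoderm markers, 2 rose and 1 fell, also adjusted over the list alone (median 0.39, adjusted p = 0.0327, and adjusted p = 0.28 with an estimated correlation). This list's call was also lost when probe sets were averaged (adjusted p = 0.21) and without untreated MEF replicate 2 (adjusted p = 0.063), S1P replicate 2 (adjusted p = 0.088) or S1P replicate 3 (adjusted p = 0.081). The Nodal, Activin and TGF-beta list was not shifted (adjusted p = 0.13). INHBA and the matrix gene TGFBI (1.42, SE 0.22) rose and LEFTY1 fell. Of its 18 genes, 3 rose and 2 fell, against 5 and 3 adjusted over the list alone.

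Of 24 pluripotency genes, 0 rose, 6 fell and 18 did not pass (8 fell adjusted over the list alone). Their median was -0.34 (adjusted p = 0.00109, and adjusted p = 0.28 with an estimated correlation). It became 0.23, against 0.51 for all genes, when the hybridization controls were made equal. The list was not shifted after quantile normalization (adjusted p = 0.49). NANOG did not pass with the hybridization controls made equal (log2 -0.35, adjusted p = 0.07). DPPA2 fell from 70.3 ± 8.69 to 24.5 ± 0.896 (log2 -1.38, SE 0.29) and likewise did not pass under that scaling. SOX2, another core factor, was at 2230 ± 252 on the S1P arrays and 2700 ± 326 on the untreated arrays, a log2 difference of -0.27 (SE 0.15, adjusted p = 0.23) that did not exceed the spread.

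Lists of cell cycle and cell survival genes were tested next. Of 32 genes of the G2 and M phases, 0 rose and 14 fell (15 adjusted over the list alone), with a median of -0.43 that became 0.14, against 0.51 for all genes, when the hybridization controls were made equal (adjusted p = 3.53e-07, and adjusted p = 0.22 with an estimated correlation). The mitotic kinase gene AURKA had a difference of -1.09 (SE 0.16) and NUSAP1, a spindle protein gene, of -0.83 (SE 0.12). AURKA did not pass when probe sets were averaged, nor NUSAP1 with the hybridization controls made equal. Of 31 genes of the G1 and S phases, 3 rose and 5 fell, as they did adjusted over the list alone, and the list was not shifted (median -0.12, or 0.45 with the hybridization controls made equal, adjusted p = 0.491). Of 13 cell cycle inhibitors, 2 rose and 0 fell, also adjusted over the list alone (median 0.38, adjusted p = 0.0305, and adjusted p = 0.39 with an estimated correlation). CDKN2B, which encodes the kinase inhibitor p15, rose from 8.93 ± 6.85 to 95.5 ± 30.0 (log2 3.09, SE 0.45), and GADD45A rose by 1.39 (SE 0.27). The list's call was lost with averaged probe sets (adjusted p = 0.12) and without untreated MEF replicate 2 (adjusted p = 0.081), untreated MEF replicate 3 (adjusted p = 0.053) or S1P replicate 1 (adjusted p = 0.10). Of 20 anti-apoptotic genes, 2 rose and 1 fell (0 and 1 adjusted over the list alone; median 0.02, adjusted p = 0.522). BCL2, an inhibitor of apoptosis, was at 71.2 ± 1.64 against 37.5 ± 5 (log2 0.86, SE 0.26, adjusted p = 0.042), but passed in 7 of the 19 alternatives that kept it. The 26 pro-apoptotic genes had a median of -0.14 and no shift (adjusted p = 0.296). With the hybridization controls made equal their median was 0.43, against 0.51 for all genes. Of the 26, 0 rose and 4 fell, also adjusted over the list alone. They included BAX and the caspase gene CASP8 (-1.15, SE 0.30), whose call was lost in 4 of 19 alternatives. The 22 p53 targets had a median of -0.06, a mean of 0.01 and no shift (adjusted p = 0.819), with 3 higher and 2 lower (3 and 4 adjusted over the list alone).

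Housekeeping and metabolic genes included some of the brightest on the arrays. Of 17 ribosomal protein genes, 16 fell and 0 rose (17 fell adjusted over the list alone). Their median was -0.51 (adjusted p = 1.54e-14, and adjusted p = 0.22 with an estimated correlation). It became -0.08 after quantile normalization and 0.07 with the hybridization controls made equal, against -0.10 and 0.51 for all genes. RPLP1 had a difference of -0.67 (SE 0.07) and RPS9 of -0.81 (SE 0.09), and neither passed with the hybridization controls made equal or with averaged probe sets. Of 25 respiratory chain genes, 16 fell and 0 rose (18 fell adjusted over the list alone). Their median was -0.48 (adjusted p = 2.48e-08, and adjusted p = 0.11 with an estimated correlation). It became 0.09, against 0.51 for all genes, with the hybridization controls made equal. COX5B, a cytochrome c oxidase subunit, fell from 2480 ± 386 to 1210 ± 46.4 (log2 -1.02, SE 0.12). The 1187 brightest of all tested genes had a median of -0.28 and the 1187 dimmest 0.01. Of 18 metallothionein and oxidative stress genes, 7 rose and 3 fell (9 and 4 adjusted over the list alone; median 0.53, adjusted p = 0.00837, and adjusted p = 0.31 with an estimated correlation). The zinc transporter SLC30A1 rose by 2.73 (SE 0.40), and the list's call was lost without the probe sets ending in _x_at (adjusted p = 0.54).

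Of 28 genes of glycolysis and hypoxia, 5 rose and 3 fell (7 and 3 adjusted over the list alone), with a median of -0.03, a mean of 0.16 and no shift (adjusted p = 0.315). VEGFA (2.07, SE 0.21) and the hypoxia-responsive ADM (1.36, SE 0.19) and NDRG1 (1.41, SE 0.26) rose. VEGFA did not pass when probe sets were averaged. Of 18 junction genes, 3 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.0919), with the desmosomal DSP at 0.96 (SE 0.15). The interferon response list was not shifted (adjusted p = 0.0775), although 4 of its 14 genes fell, also adjusted over the list alone. Its median of -0.25 became 0.32, against 0.51 for all genes, with the hybridization controls made equal. IFITM1 (-1.13, SE 0.12) and IFITM2 (-1.08, SE 0.14) were among those that fell, and members of this family share sequence, so their probe sets may not separate them. The lists for unfolded protein and amino acid stress (adjusted p = 0.0715), heat shock (adjusted p = 0.306, median 0.02 and mean -0.12) and cholesterol synthesis (adjusted p = 0.785, median 0.01 and mean -0.02) were not shifted.

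Of 24 genes for S1P receptors and sphingolipid metabolism, 2 rose and 1 fell, also adjusted over the list alone, and the list was not shifted (median 0.15, adjusted p = 0.102). The receptor gene S1PR1 was at 58.1 ± 20.2 on the S1P arrays and 23.1 ± 2.72 on the untreated arrays (log2 1.16, SE 0.33, adjusted p = 0.029), a call that was lost in 7 of 20 alternatives. S1PR2 (0.08, SE 0.27), S1PR3 (0.02, SE 0.24), S1PR5 (-0.07, SE 0.40) and SPHK1, which makes S1P (0.66, SE 0.41), did not pass. S1PR4 was below the filter on dim genes, with signals of 15.6 ± 19.3 and 4.73 ± 2.71. PLPP1, a lipid phosphatase, had a difference of -0.67 (SE 0.18, adjusted p = 0.02) and passed in 14 of 21 alternatives.

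**Figure D3:**
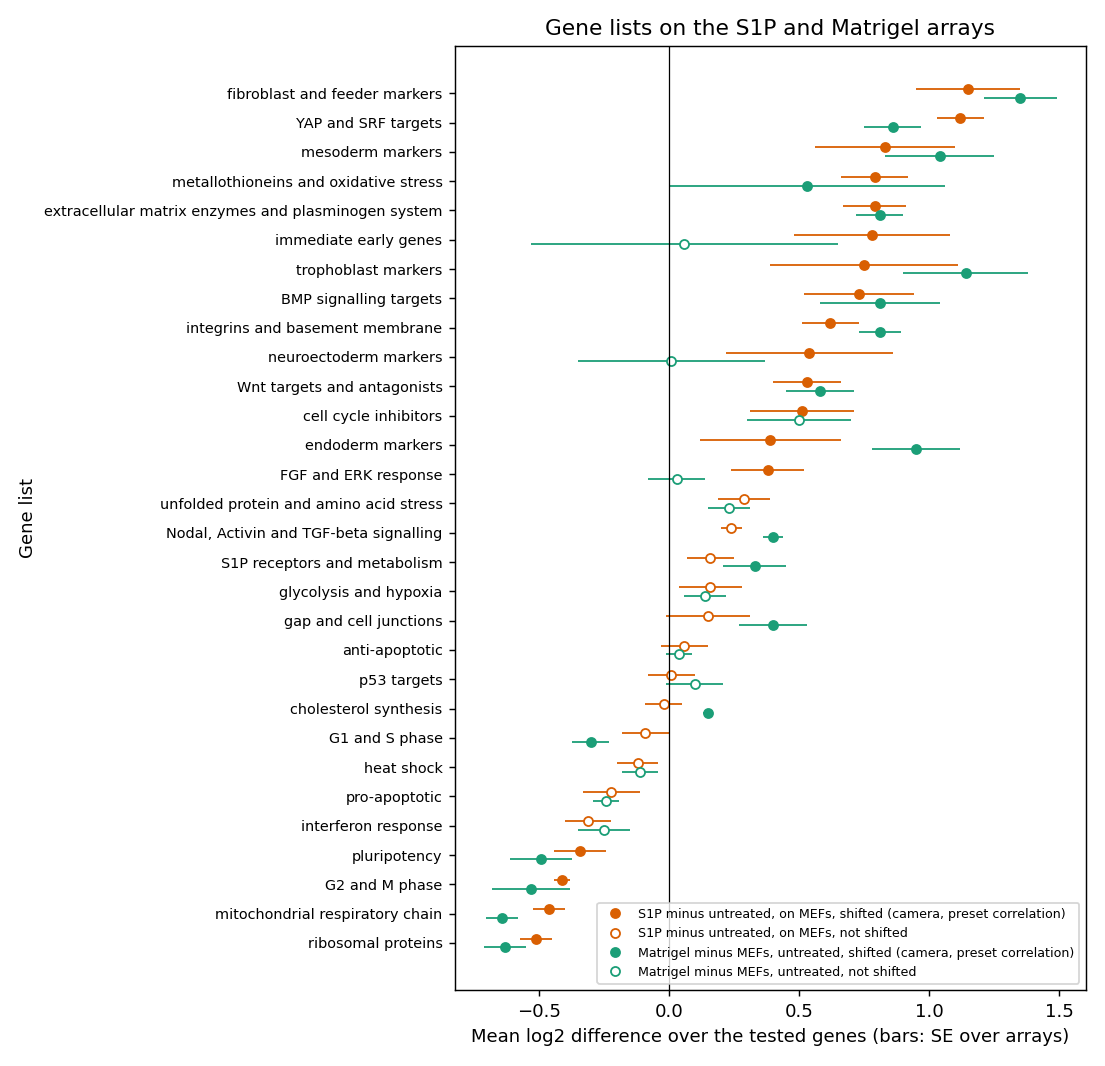
Mean log2 difference of 30 gene lists fixed in advance, for S1P against untreated cells on MEFs and for Matrigel against MEFs. Bars are standard errors over arrays, and filled points were shifted by camera with a preset correlation. The fibroblast and feeder list had means of 1.15 and 1.35 and the ribosomal list of -0.51 and -0.63. With the hybridization controls made equal the ribosomal median for S1P was 0.07, against 0.51 for all genes.

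The second comparison asked how untreated cells on Matrigel (2 arrays) differed from untreated cells on MEFs (3 arrays). As lists, fibroblast and basement membrane markers were shifted up on the Matrigel arrays with a preset correlation, and G2 and M phase and ribosomal genes down. With an estimated correlation these calls were lost (adjusted p = 0.12 for the first 2 and adjusted p = 0.17 for the others). AHNAK, a large scaffold protein gene, had a signal of 1060 ± 141 (SD, n = 2) on the Matrigel arrays and 95.3 ± 30.9 (n = 3) on the untreated MEF arrays (log2 3.47, SE 0.27, adjusted p = 5.9e-05). The fibrinogen chain genes FGA (3.59, SE 0.76, adjusted p = 0.005) and FGG (3.47, SE 0.64, adjusted p = 0.0021) rose. NANOG fell from 3080 ± 192 to 1630 ± 192 (log2 -0.92, SE 0.11, adjusted p = 0.00022) and passed in all 21 alternatives.

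Of 11865 genes tested, 2637 passed, with 1004 higher and 1633 lower on the Matrigel arrays, and 568 and 428 of these differed by a log2 of more than 1. The median of all genes was -0.10. With the hybridization controls made equal it was 0.30, and 2456 genes passed, 2176 of them higher. The count was 1539 with array medians set equal (median of all genes -0.22), 1368 without Matrigel replicate 2 and 1616 without Matrigel replicate 3.

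The largest rises also included MIR181A2HG, a microRNA host gene (132 ± 57.9 against 4.3 ± 3.05, log2 4.03, SE 0.61), SPRY4-IT1 (114 ± 8.56 against 4.33 ± 1.76, log2 3.84, SE 0.36) and LOC114224 (3.32, SE 0.55). EIF3C, a translation initiation factor subunit, was at 111 ± 6.86 against 8.1 ± 7.16 (log2 3.45, SE 0.50), and it has the near-identical copy EIF3CL, so which copy was measured is uncertain. The untreated signals of MIR181A2HG, SPRY4-IT1 and EIF3C were low, so the size of these differences depends on the offset. TOP6BL, a meiotic recombination gene, had a difference of 3.51 (SE 0.32), with its 1 other probe set above the filter moving the opposite way. Large falls were seen for NPM3 (-2.79, SE 0.31), the cytidine deaminase CDA (-2.84, SE 0.55), GLDN (-2.44, SE 0.45), PRMT1 (-2.19, SE 0.23) and POU5F1P3 (-2.21, SE 0.29), the last with the same uncertainty as above. The Matrigel signals of CDA (8.1 ± 9.62) and GLDN (5.6 ± 2.26) were low too, with the same limit. PRMT1 did not pass when probe sets were averaged. The immediate early factor EGR1 was at 146 ± 163 against 866 ± 458 (log2 -3, SE 0.65, adjusted p = 0.0056), and did not pass without Matrigel replicate 2 (log2 -1.53). COPE (-2.40, SE 0.63) did not pass without the intensity trend or without either Matrigel replicate, and TUBA4B (-2.24, SE 0.52) did not pass without Matrigel replicate 3 (log2 -1.19). With averaged probe sets the differences of SPRY4-IT1, TOP6BL, GLDN, EGR1 and COPE were over 1.5 times smaller but passed, as were those of FGA, COL1A1, LOX, COL4A5, APOB and GINS2.

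Camera called 19 of 30 lists shifted, 14 up and 5 down, and fry called 16. Of 28 fibroblast and feeder markers, 17 rose and 0 fell (19 adjusted over the list alone) on the Matrigel arrays, whose descriptions name no feeder layer and whose poly-A controls were 4.02 higher, with a median of 1.43 (adjusted p = 1e-11, and adjusted p = 0.12 with an estimated correlation). COL1A1 rose from 420 ± 137 to 2020 ± 80.8 (log2 2.31, SE 0.23) and LOX by 3.05 (SE 0.31). Of 22 integrin and basement membrane genes, 12 rose and 0 fell (13 adjusted over the list alone; median 0.91, adjusted p = 7.36e-09, and adjusted p = 0.12 with an estimated correlation). They included ITGAV (1.32, SE 0.12) and the basement membrane collagens COL4A1 (1.23, SE 0.15) and COL4A5 (1.24, SE 0.17). Of 25 YAP and SRF targets, 13 rose (15 adjusted over the list alone; median 0.51, adjusted p = 7.36e-09, and adjusted p = 0.12 with an estimated correlation), among them CRIM1 (1.90, SE 0.20) and F3 (2.01, SE 0.26). Of 19 matrix enzymes and plasminogen genes, 8 rose (10 adjusted over the list alone; median 0.82, adjusted p = 1.56e-05, and adjusted p = 0.12 with an estimated correlation), with ADAMTS1, a matrix protease, at 1.87 (SE 0.29) and the cathepsin gene CTSL at 0.98 (SE 0.18). Of 18 junction genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.31, adjusted p = 0.000731, and adjusted p = 0.17 with an estimated correlation), with DSP at 1.09 (SE 0.17).

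Of 17 endoderm markers, 8 rose and 0 fell, also adjusted over the list alone (median 0.56, adjusted p = 0.00058, and adjusted p = 0.16 with an estimated correlation). AFP, the fetal serum protein alpha-fetoprotein, rose from 321 ± 192 to 2040 ± 510 (log2 2.89, SE 0.63, adjusted p = 0.0062) and the apolipoprotein gene APOB by 2.72 (SE 0.59, adjusted p = 0.0056), but neither passed without Matrigel replicate 3. The list's call was lost with averaged probe sets (adjusted p = 0.068). Of 12 trophoblast markers, 6 rose (7 adjusted over the list alone; median 0.93, adjusted p = 1.56e-05, and adjusted p = 0.17 with an estimated correlation), among them the placental growth factor PGF (1.46, SE 0.22) and IGFBP3 (2.23, SE 0.29). Of 12 mesoderm markers, 7 rose and 1 fell, also adjusted over the list alone (median 1.13, adjusted p = 0.000554, and adjusted p = 0.17 with an estimated correlation), with SNAI2 at 2.05 (SE 0.39). The 18 neuroectoderm markers had a median of 0.02 and no shift (adjusted p = 0.724), and 2 fell, also adjusted over the list alone, among them the neuronal tubulin TUBB3 (-1.06, SE 0.15). Of 16 BMP targets, 8 rose, also adjusted over the list alone (median 0.88, adjusted p = 0.000111, and adjusted p = 0.17 with an estimated correlation), with BAMBI at 1.70 (SE 0.18), BMP2 at 1.71 (SE 0.17) and GREM1 at 2.20 (SE 0.24). Of 15 Wnt targets and antagonists, 4 rose and 1 fell, also adjusted over the list alone (median 0.37, adjusted p = 0.00658, and adjusted p = 0.17 with an estimated correlation), with WNT5A at 1.83 (SE 0.32), FRZB at 1.71 (SE 0.31) and LGR5 at 1.77 (SE 0.26). Of 18 Nodal, Activin and TGF-beta genes, 4 rose and 1 fell, also adjusted over the list alone (median 0.13, adjusted p = 0.0457, and adjusted p = 0.17 with an estimated correlation), with TGFBI at 2.31 (SE 0.24) and LTBP1 at 0.93 (SE 0.17). This list's call was lost when genes below the 60th percentile of mean signal were left out (adjusted p = 0.12), and without untreated MEF replicate 1 (adjusted p = 0.093) or Matrigel replicate 3 (adjusted p = 0.089).

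Of 24 pluripotency genes, 10 fell and 0 rose on the Matrigel arrays (13 fell adjusted over the list alone; median -0.50, adjusted p = 0.000152, and adjusted p = 0.17 with an estimated correlation), and the shift was lost after quantile normalization (adjusted p = 0.11). SOX2 was at 1880 ± 531 (n = 2) against 2700 ± 326 (n = 3), a log2 difference of -0.54 (SE 0.16, adjusted p = 0.03) that passed in 13 of 21 alternatives and was -0.25 without Matrigel replicate 2 and -0.83 without Matrigel replicate 3. Of 32 genes of the G2 and M phases, 17 fell and 0 rose (19 fell adjusted over the list alone; median -0.54, adjusted p = 4.06e-07, and adjusted p = 0.17 with an estimated correlation), with UBE2C, a mitotic ubiquitin-conjugating enzyme, at -1.48 (SE 0.19), the securin PTTG1 at -1.09 (SE 0.14) and CKS2 at -0.93 (SE 0.12). The 31 genes of the G1 and S phases had a median of -0.31 (adjusted p = 0.022, and adjusted p = 0.29 with an estimated correlation). It became 0.09, against 0.30 for all genes, when the hybridization controls were made equal. Of the 31, 8 fell and 1 rose, also adjusted over the list alone. The replication factors GINS2 (-1.49, SE 0.17) and CDT1 (-1.15, SE 0.20, or -2.27 without probe sets ending in _x_at) were among them, and the list was not shifted after quantile normalization (adjusted p = 0.30) or without untreated MEF replicate 2 (adjusted p = 0.071) or Matrigel replicate 3 (adjusted p = 0.063). All 17 ribosomal protein genes fell, also adjusted over the list alone (median -0.58, adjusted p = 1.41e-12, and adjusted p = 0.17 with an estimated correlation), with RPL19 at -1.10 (SE 0.11). After quantile normalization the mean of this list went from -0.63 to -0.22 (SE 0.039), against a median of -0.17 for all genes. It was still shifted with the preset correlation (adjusted p = 0.0052), but not with an estimated one (adjusted p = 0.12). Of 25 respiratory chain genes, 17 fell and 0 rose (20 and 1 adjusted over the list alone; median -0.63, adjusted p = 7.36e-09, and adjusted p = 0.12 with an estimated correlation), with COX5B at -1.21 (SE 0.14).

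Of 24 genes for S1P receptors and sphingolipid metabolism, 5 rose and 0 fell (4 adjusted over the list alone; median 0.30, adjusted p = 0.000843, and adjusted p = 0.17 with an estimated correlation). These were enzymes, among them the S1P lyase gene SGPL1 (0.77, SE 0.18) and the S1P phosphatase gene SGPP1 (0.89, SE 0.21), and both were lost with array medians set equal and without Matrigel replicate 2. With averaged probe sets SGPL1 was at 0.03 (adjusted p = 0.96). S1PR1 (0.92, SE 0.36, adjusted p = 0.087), S1PR2 (0.30, SE 0.31), S1PR3 (0.16, SE 0.26), S1PR5 (0.19, SE 0.45) and SPHK1 (0.41, SE 0.46) did not pass. The cholesterol synthesis list (median 0.23, adjusted p = 0.0274, and adjusted p = 0.17 with an estimated correlation) and the metallothionein list (median 0.69, adjusted p = 0.022, and adjusted p = 0.34 with an estimated correlation) were shifted up. The first call was lost with array medians set equal (adjusted p = 0.14) and without Matrigel replicate 3 (adjusted p = 0.065). The second was lost without probe sets ending in _x_at (adjusted p = 0.11), and without Matrigel replicate 3 its median was -0.01 (adjusted p = 0.76). Of 19 cholesterol genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), and of 18 metallothionein and oxidative stress genes 3 rose and 3 fell (5 and 3 adjusted over the list alone). The other lists were not shifted, namely immediate early genes (adjusted p = 0.111), FGF and ERK response (0.518, median -0.11 and mean 0.03), anti-apoptotic (0.518), pro-apoptotic (0.36), p53 targets (0.498, median -0.07 and mean 0.10), cell cycle inhibitors (0.0757), glycolysis and hypoxia (0.306), unfolded protein and amino acid stress (0.109), heat shock (0.425) and interferon response (0.331).

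The third comparison set the Matrigel arrays directly against the S1P arrays. These groups differed both in surface and in treatment, so a difference cannot be assigned to either alone. The Matrigel and S1P arrays overlapped in the mean of the poly-A controls. They did not overlap in dap, the brightest of these (lowest 9.35 on Matrigel, highest 9.29 with S1P), in the ratios of 3' to 5' signal for actin (9.47 and 9.9 against 6.48 to 7.32) and GAPDH (1.64 and 1.73 against 1.5 to 1.58), or in the hybridization controls, whose lowest mean was 8.58 on the Matrigel arrays and whose highest was 8.55 on the S1P arrays. A single gene passed. CCDC152 was at 1320 ± 239 (SD, n = 2) on the Matrigel arrays and 440 ± 86.8 (n = 3) on the S1P arrays (log2 1.58, SE 0.20, adjusted p = 0.037). Its gene overlaps SELENOP, its probe set ends in _x_at, and the call held in 7 of 20 alternatives. By limma 1443 genes had an unadjusted p under 0.05, where 593 would be expected by chance. Without passing, PPIC (1.07, SE 0.20), AHNAK (1.39, SE 0.27) and the quinone reductase NQO1 (1.33, SE 0.26) were higher on the Matrigel arrays (adjusted p = 0.24 each). The dynein light chain DYNLL1 (-0.63, SE 0.10, adjusted p = 0.2), TUBB3 (-0.76, SE 0.15), BEX2 (-0.76, SE 0.15) and PHLDA1 (-1.35, SE 0.29) were lower (adjusted p = 0.24 for the last 3). PHLDA1 was at -0.72 without Matrigel replicate 2 (adjusted p = 0.93) and at -1.98 without Matrigel replicate 3 (adjusted p = 0.012). AHNAK passed without untreated MEF replicate 1, and DYNLL1 after quantile normalization and without Matrigel replicate 3.

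As lists, 13 of 30 were shifted between the Matrigel and S1P arrays with the preset correlation. With an estimated correlation 0 were (smallest adjusted p = 0.38), and fry called 0. Among lists higher on Matrigel were integrins and basement membrane (median 0.31, adjusted p = 0.000536), junctions (0.25, adjusted p = 0.00154), S1P receptors and metabolism (0.24, adjusted p = 0.00154), cholesterol synthesis (0.26, adjusted p = 0.00162), endoderm (0.32, adjusted p = 0.00192), trophoblast (0.34, adjusted p = 0.00644) and fibroblast markers (0.33, adjusted p = 0.00672). With an estimated correlation their adjusted p ranged from 0.38 to 0.50. Immediate early genes (median -0.59, adjusted p = 8.94e-05) and neuroectoderm markers (-0.53, adjusted p = 0.00103) were lower on Matrigel (adjusted p = 0.47 for both with an estimated correlation). So were the G1 and S phase (-0.21, adjusted p = 0.00162), respiratory chain (-0.18, adjusted p = 0.00644), FGF and ERK response (-0.22, adjusted p = 0.0266) and ribosomal lists (-0.07, adjusted p = 0.0281). Their adjusted p with an estimated correlation ranged from 0.38 to 0.68. The immediate early call rested on Matrigel replicate 2, without which the median was -0.10 (adjusted p = 0.13). Without S1P replicate 1 the fibroblast (adjusted p = 0.13), trophoblast (adjusted p = 0.16), FGF and ERK (adjusted p = 0.29), respiratory chain (adjusted p = 0.099) and ribosomal calls (adjusted p = 0.43) were lost, and 8 lists were shifted. Without Matrigel replicate 3 the endoderm (adjusted p = 0.053), trophoblast (adjusted p = 0.15) and FGF and ERK calls (adjusted p = 0.08) were lost, and without Matrigel replicate 2 the ribosomal call (adjusted p = 0.89). Adjusted over the list alone, 8 immediate early genes and 3 neuroectoderm markers were lower, and 3 integrin and basement membrane genes, 4 cholesterol genes, 2 endoderm markers and 3 trophoblast markers were higher. So adjusted, 1 fibroblast marker was lower and 0 higher, against the upward shift of that list, and 2 YAP and SRF targets, 1 FGF and ERK gene and 1 ribosomal gene were lower. Of the matrix enzymes 2 were higher and 2 lower, of the Nodal list 2 and 1, of the Wnt list 1 and 1, and of the metallothionein list 1 and 0.

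The S1P and Matrigel differences were set side by side, since both were measured against the same 3 untreated MEF arrays. Across the 11865 genes, which are not independent replicates, the log2 differences had a Pearson correlation of 0.792, against 0.448 in simulations with no effect and the same shared arrays. Their covariance was 0.285, against 0.0391 in the simulations, and 79.5% of genes had the same sign against 64.8%. Both comparisons called 506 genes higher, where independent lists would share 63.4, and 931 lower, where they would share 161. The values for independent lists leave out the shared arrays, and no overlap was simulated with them. THBS1, CRIM1, COL1A1, GREM1 and CDKN2B rose in both and NPM3 and PRMT1 fell in both, and 0 genes were called in opposite directions. The 3 untreated arrays cannot be divided so that each part keeps 2, so part of the excess in overlap may come from the shared arrays. The simulated correlation and covariance hold the random spread of these arrays, but not a difference in how their RNA was handled.

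**Figure D4:**
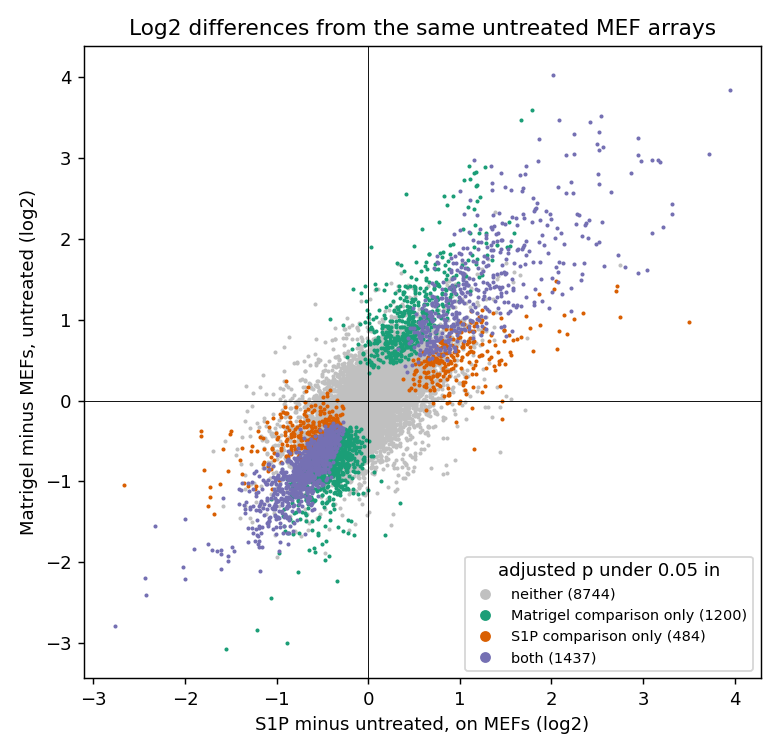
Log2 differences of 11865 genes from the same untreated MEF arrays, S1P on the horizontal axis and Matrigel on the vertical axis, with 1 point per gene. Both comparisons called 1437 genes, the S1P comparison alone 484 and the Matrigel comparison alone 1200, and the correlation across genes was 0.792.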

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

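The tests of explanations below were chosen only after the results were seen, except the count of other splits of the arrays, which was planned.

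Control transcripts outside the main measurement showed a signal that differed between groups. Probe sets for bacterial poly-A controls were higher by a log2 of 3.55 (SE 0.29) on the S1P arrays and by 4.02 (SE 0.15) on the Matrigel arrays than on the untreated MEF arrays.

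The untreated MEF arrays stood apart from both other groups in human genes too, with a mean correlation of 0.933 with the S1P arrays and 0.92 with the Matrigel arrays, against 0.954 between those. The covariance of the S1P and Matrigel differences exceeded the simulated value by 0.246, which alike responses to S1P and to Matrigel would give. A separate labelling run of the untreated arrays could give it too, and the poly-A difference of 3.55 shows that the RNA of the groups was not handled alike. No untreated MEF array had the control signal of the other arrays, so these explanations cannot be told apart. Of the 10 splits of the 6 MEF arrays into 3 and 3, 1 (the real one) gave 1921 genes and the highest of the others 0, and 10 splits are too few for a share under 0.05.

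The ribosomal, respiratory chain and G2 and M phase lists were shifted down on the S1P arrays with a preset correlation (16 of 17, 16 of 25 and 14 of 32 genes passed), but not with an estimated one (adjusted p = 0.22, adjusted p = 0.11 and adjusted p = 0.22). With the hybridization controls made equal, which moves all genes alike, their medians were 0.07, 0.09 and 0.14, below the 0.51 of all genes. A candidate explanation is a difference between arrays that depends on intensity. Quantile normalization gives all arrays the same distribution of signals. After it the mean of the respiratory chain list was -0.27 (SE 0.04) and that of the G2 and M phase list -0.33 (SE 0.03). Both were still shifted by camera with the preset correlation, but not with an estimated one (adjusted p = 0.20 and adjusted p = 0.24). The lists were not set against genes of like signal, so the test cannot decide whether intensity accounts for these shifts. The ribosomal mean went from -0.51 (SE 0.06) to -0.11 (SE 0.0048), still below 0 by over 2 SE but near the median of all genes, then -0.10. Quantile normalization draws the brightest signals of the arrays together, so this SE may understate the spread between replicates. The ribosomal list was no longer shifted with the preset correlation (adjusted p = 0.052). A difference that depends on intensity stays open for all 3 lists. The respiratory chain and G2 and M phase means stayed below the median of all genes of -0.10. The labelling run and a response of the cells stay open for all 3.

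The fibroblast and feeder list was shifted up on the S1P and Matrigel arrays with a preset correlation (15 and 17 of 28 genes passed), but not with an estimated one (adjusted p = 0.11 and adjusted p = 0.12). RNA carried over from mouse feeder cells would be lowest without feeders, and the list was higher by a mean log2 of 1.35 (SE 0.14) on the Matrigel arrays. This argues against carry-over there only if these arrays had no feeders. Their titles and descriptions name Matrigel, but the treatment text names MEFs. The rise is also the pattern to be explained, so it is no separate test, and the RNA of the groups was not handled alike. For the S1P arrays the list differed from the Matrigel arrays by 0.20 (SE 0.13), which leaves carry-over open. A share of differentiated cells could raise the list and lower pluripotency genes. Their mean after quantile normalization was -0.36 (SE 0.12) on Matrigel and -0.20 (SE 0.11) with S1P, the latter within 2 SE of 0. The medians of all genes were then -0.17 and -0.10, so part of both values is shared by other genes. A share of differentiated cells stays open. The labelling run stays open as well. Of the 30 markers, 28 were above the filter in these cells and 7 stand in other lists too, and the most abundant on the untreated arrays were VIM (2110 ± 147, against 2410 ± 57.5 with S1P and 1940 ± 107 on Matrigel) and FN1 (1450 ± 301, against 2970 ± 635 and 4280 ± 18.3).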

How the results depend on the processing

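Scaling to the hybridization controls was chosen after the data were seen, and every other alternative here was planned.

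Between S1P and untreated cells, 1921 genes became 882 with array medians set equal, 962 without the intensity trend, 1111 with the mean of all probe sets, 4279 with all probe sets tested and 4141 with the hybridization controls made equal, of which 98.8% were higher against 39%. Leaving out 1 array gave 1178 (untreated MEF replicate 2) to 1834. For Matrigel against MEFs, 2637 became 1539 with medians equal and 6320 with all probe sets tested, and 88.6% of 2456 were higher with the hybridization controls made equal, against 38.1%. Leaving out 1 array gave 1368 (Matrigel replicate 2) to 2747. For Matrigel against S1P, the count of 1 became 2 after quantile normalization, 4 with all probe sets tested, and 0 with medians equal, with only the arrays of the 2 groups, without the trend, with the mean of probe sets, without _x_at probe sets, with the replicate block and with the hybridization controls made equal. It was 0 to 19 without 1 array, the 19 without Matrigel replicate 3 sharing 0 genes with the full fit. Where an arm then had 1 array, that array was assumed to vary like the others. The cause of these changes was not tested, except that tests of all probe sets count several per gene.

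With an estimated correlation 0 lists were shifted in each comparison, and fry called 0 for Matrigel against S1P. Leaving out 1 array gave 16 to 19, 15 to 20 and 8 to 15 lists in the 3 comparisons, the 8 without S1P replicate 1. The correlation of the S1P and Matrigel differences was 0.684 with no filter and 0.683 (without Matrigel replicate 3) to 0.809 without 1 array, 0.739 without S1P replicate 3. Same-numbered untreated and S1P arrays correlated in their deviations by 0.12, -0.01 and 0.10, and those with different numbers by -0.17 to 0.10. With so few arrays these values cannot show whether the numbers pair the samples. The replicate block gave 1971, 2445 and 0 genes and 18, 20 and 14 lists.

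Of 94 genes taken by the naming rule that passed between S1P and untreated cells, 42 passed in every alternative, of 98 for Matrigel 47, and of 1 for Matrigel against S1P 0. Some signs reversed. Making the hybridization controls equal moves all genes alike, by the control difference (-0.57 for S1P and -0.40 for Matrigel), which accounts for the reversals under it. The S1P log2 differences became 0.04 (FDPS), 0.09 (PCNA), 0.28 (GJA1), 0.12 (HSP90AA1), 0.13 (HSPD1), 0.14 (PRDX1), 0.11 (CD24), 0.05 (RPS16) and 0.17 (PSAT1), and the Matrigel ones 0 for HSP90AA1, HSPD1 and CD24 after rounding. The cause of the other reversals was not tested. After quantile normalization they became 0.14 (GJA1) and 0.01 (HSPD1) for S1P and 0.03 (HSP90AA1), 0.04 (HSPD1), 0.01 (PRDX1) and 0.04 (CD24) for Matrigel. With the mean of probe sets HSPD1 was 0.35 for S1P and 0.32 for Matrigel, and ATF3 was -0.17 for Matrigel.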

Other observations

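The observations below were all chosen after the values were seen, and so were the genes named in them.

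The serum protein gene AFP was at 1680 and 2400 on the Matrigel arrays, at 881 and 1020 on S1P replicates 2 and 3, and at 210 on S1P replicate 1, within the untreated range of 102 to 460. FGA followed the same order, with 224 and 302 on Matrigel, 111 and 146 on S1P replicates 2 and 3 and 20.8 on S1P replicate 1, and FGG was at 257 and 458, 167 and 186, and 26.3. In the Matrigel against MEF comparison, FGB (log2 2.83, SE 0.65, adjusted p = 0.00816), TTR (2.52, SE 0.56, adjusted p = 0.00635) and APOA1 (2.13, SE 0.57, adjusted p = 0.0181) rose too. In the S1P comparison the same genes did not pass, at 1.18 for FGB, 1.22 for TTR and 1.03 for APOA1.

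The Matrigel arrays differed from each other in some immediate early genes, EGR3 and EGR1 among them, while KLF6 varied less (633 ± 72.8, SD, n = 2). EGR3 was at 14.8 on Matrigel replicate 2 and 276 on replicate 3, and EGR1 at 30.8 and 262. On the S1P arrays EGR3 was between 266 and 537, and on the untreated MEF arrays between 18.8 and 50.

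Among neuroectoderm markers, SOX1 was at 78.6 ± 1.48 on the Matrigel arrays and 190 ± 25.8 on the S1P arrays (log2 -1.23, SE 0.38), and FABP7 at 178 ± 111 and 333 ± 56.6 (-1.02, SE 0.31). Neither passed over all genes (adjusted p = 0.28 for both), and both passed adjusted over the list alone (adjusted p = 0.04 for both). LEFTY1 was at 344 ± 26.2 on the Matrigel arrays and 114 ± 36.3 on the S1P arrays (log2 1.61, SE 0.39, adjusted p = 0.24).

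Differences also went with gene length across genes, which are not independent replicates. The Spearman correlation of the log2 difference with gene length was 0.18 for S1P, 0.22 for Matrigel and 0.13 for Matrigel against S1P. Genes of at most 9827 bp, the shortest 20%, had medians of -0.20, -0.32 and -0.13.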
